A study of Homo sapiens with 20 samples.

How the data were processed

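Gene expression was measured in MCF-7 cells, an estrogen receptor positive human breast cancer line, on 2-colour Agilent 60-mer oligonucleotide arrays. Cells had been treated for 24 h with vehicle, 1 µM MG132 (a peptide aldehyde inhibitor of the proteasome), 1 nM dexamethasone (a synthetic glucocorticoid), 10 nM 17β-estradiol (E2), MG132 plus dexamethasone or E2 plus MG132, per the labels. The labels' extract protocols call the control vehicle-treated, whereas the series' design text calls it untreated. Each treated RNA was hybridised against control RNA of the same biological experiment, once with the treated RNA in Cy5 and once in Cy3. The 20 arrays therefore gave 5 treatments in 2 experiments, with a dye-swapped pair of arrays for each treatment and experiment. No array compared a control with another control, so each treated sample was measured only as a ratio to its control.

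The scanner files hold, per the file headers, the output of Agilent Feature Extraction A.7.1.1, a program that quantifies scanned array images. The deposited intensity of a spot is its mean pixel brightness in green (Cy3) or red (Cy5), with the median of its local background beside it. The files also hold processed intensity values, which per the file headers were background-subtracted and dye-normalized with a linear and a LOWESS step by the software. Their log ratio is, per the file headers, the log10 of processed red over processed green. The deposited value table of the series holds the same log10 ratio with the sign turned. No aligner or genome build applies to these arrays.

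From the mean and background intensities, both channels were corrected with normexp and an offset of 50 and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and spots with an outlier mark were then left out, and saturated spots were kept. Each array's log2 ratio was turned to treated over control. The ratio of spots of the same probe was averaged, and the arrays of a dye-swapped pair were averaged to 1 replicate ratio, which needed both arrays. Each treatment so had n = 2 where both pairs were usable and n = 1 where only 1 was. Of 17086 gene probes on 17986 spots, 16467 were well above background in all 4 treated channels of some treatment or in at least 16 of the 20 control channels, and 16085 of these gave at least 1 ratio for every treatment and were tested. Between 529 and 964 of them had a single ratio for a given treatment, and 32 of the 227 and 53 of the 516 interaction calls involved such a treatment. A complete set of 10 dye-balanced replicate ratios was present for 13275 probes, on which gene list tests and correlations were run. Counts and medians of a list cover all its measured members. Camera tested only those with such a complete set, which could have another median.

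The 5 treatments were fitted together with lmFit and eBayes in limma, with a shared estimate of the spread (5 residual and 4.99 prior degrees of freedom). A ratio against 0 tested each treatment against control. Each experiment had its own control RNA, so the spread of the ratios holds the control's spread, which could not be estimated apart. All treatments of an experiment share this control, so their residuals are not independent and the degrees of freedom are overstated. Differences between treatments of these ratios gave the other comparisons. The control cancels between 2 treatments, and an interaction keeps 1 control term. The shared estimate of the spread holds the control's spread for every ratio, so the errors of these comparisons may be too wide. The interaction was the effect of a hormone added to MG132 minus its effect alone. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The labels speak of 2 biological experiments, so the replicates are separate experiments, but their small number limits the precision. On data simulated for 16000 probes with a spread set in advance, E2 against control recovered 20% of the probes changed by 0.5 on the log2 scale, 92% of those changed by 1 and 100% of those changed by 2, and E2 with MG132 against MG132 recovered 0%, 68% and 98%. Of the calls, 6.47% and 2.21% were false. The simulated spread was set wider than that fitted here (median SE 0.088 and 0.124), so these shares need not hold for these arrays. Camera found a list shifted in the simulation and called 0 of 20 unchanged lists. The simulated genes varied independently, so this cannot show how camera's preset correlation performs on genes that vary together.

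Lists of genes were fixed before the data were examined and tested with camera in limma at a preset inter-gene correlation of 0.01, with the brightest probe of each gene and Benjamini-Hochberg adjustment over the lists of a comparison. They covered estrogen-induced and estrogen-repressed genes, glucocorticoid-induced genes, proteasome subunits, ubiquitin conjugation and removal, chaperones, the unfolded protein and integrated stress response, the NRF2 response, metallothioneins, p53 targets, apoptosis, cell cycle, histones, chromatin-modifying enzymes, nuclear receptors and their coregulators, NF-kB targets, interferon-stimulated genes, autophagy, cholesterol synthesis, ribosomal proteins, and markers of luminal, basal, fibroblast and leukocyte cells. Estimated correlations, the mean of all probes of a gene, and fry, which tests whether the genes of a list move on balance one way, were alternatives. Named genes followed a rule fixed at the same time. It took the 10 highest and 10 lowest called changes of the 3 single treatments (5 and 5 in other comparisons) with the same sign in all 4 arrays and 1 gene symbol that was not a bare clone or reading-frame name. It added up to 4 called members of each list described with the largest moderated t, or up to 2 uncalled members with the largest change, and 20 index genes given whatever their result. Of the index genes, 18 were fitted; GREB1 had no probe under its symbol and FKBP5 too few usable spots. PSMB10, PSME1, PSME2 and XBP1 with MG132 were named after their values were seen.

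Gene names came from the files and were updated through a RefSeq gene table of assembly GRCh38.p14, which was used for names only, and positions of probes were not available. Of the 17086 probes, 7527 carried a current symbol and 2972 an older symbol with 1 current match. Another 303 matched several genes and 2 conflicted, 2675 kept the name in the file and 3607 had no gene name. Where probes of a named gene differed, both values are given. Histone and metallothionein genes are near-identical in parts, and 60-mer probes can bind several of them, so that single members of these families are uncertain.

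Median green intensity per array lay between 238 and 611 and median red intensity between 144 and 461. Between 97.5% and 99.9% of probes were well above background in green and between 89.8% and 99.9% in red, and 6 to 85 spots were saturated per array and channel. Dye bias was large. The mean Cy5 over Cy3 ratio over all arrays had an SD of 0.30 (log2) across probes and lay beyond 1 for 130 probes. Over probes, the arrays of a swapped pair, both turned to treated over control, correlated between −0.40 and 0.61 (median 0.44), and the 4 pairs of dexamethasone and E2 lay below 0 because the dye bias of single arrays exceeded these treatments' effects. After averaging of the pairs, which cancels a constant dye bias, the replicate ratios of both experiments correlated at 0.94 for MG132, 0.47 for E2, 0.74 for dexamethasone, 0.96 for E2 with MG132 and 0.90 for MG132 with dexamethasone.

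The labels number the 2 experiments, whose treatments share control RNA, so the numbers pair the samples. The deviations of 2 treatments from their means correlated between −0.11 and 0.75 over the 10 pairs of treatments (median 0.27), and 7 pairs lay above 0.1. The experiment number as a replicate block was fitted as an alternative, and its counts stand beside results that it moved by over 1.5 times. The arrays had been extracted on 6 days and lay on 20 slides, so that the slide could not be a block. Extraction day was fitted on the 20 arrays as a separate dye bias for each day, on the 13275 complete probes. The dye-swapped pair was a random block in this fit. It is called day as a block below, and it removes no shift of the treated over control ratio by day. Both dexamethasone pairs were each extracted within 1 day, so the fit of its 2 replicates alone is a test within days. The day term cancels within such pairs, so its list medians stayed at 100% by construction. E2 with MG132 had 1 replicate within a day and the other treatments none, so that no such test could be made for them. Other alternatives were no background subtraction, the processed signals, median centring, Aquantile scaling, no filter or a strict filter on dim probes (14415 probes), the deposited value table, the arrays as units with a dye term, only the treatments of a comparison, arrays of a single dye orientation, eBayes with trend and robust, and leaving out each replicate. Removal of a dye profile was added after seeing the data.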

Results

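RNA abundance was measured on 20 arrays in MCF-7 breast cancer cells after 24 h of exposure. There were 2 replicate ratios for each of MG132, E2, dexamethasone, E2 with MG132 and MG132 with dexamethasone, each against the control of the same experiment. Median intensity per array lay between 238 and 611 in green and between 144 and 461 in red, and the small number of arrays limits the precision. Values below are log2 ratios ± SE from limma with n = 2 per treatment at 13275 of the 16085 tested probes, and adjusted p-values are limma's after Benjamini-Hochberg adjustment over 16085 probes. Every called gene named had the same sign in each usable array of its comparison unless stated. Genes given as highest or lowest, or as raised or lowered most, are those among genes called with the same sign in all 4 arrays, and a gene with fewer usable arrays can lie beyond them. The other 2810 probes had a single replicate ratio in at least 1 treatment, which was assumed to vary like the rest. Among genes named below n was 1 for NR2F1 and PSME2 with MG132, ERBB2, RPS6 and CRYAB with E2, KRT6A and OAS2 with dexamethasone, FKBP4 with E2 and MG132, and PGR, IFIT1, IFI44, IER3, KRT6A, PSMB1, SQSTM1 and USP14 with MG132 and dexamethasone. The spread of the ratios holds that of the control cultures, which could not be told apart from that of the treated ones. All treatments of an experiment share its control, so their errors are not independent. The design asked how MG132, E2 and dexamethasone each changed expression, and how the responses to MG132 and to either hormone changed in their combination.

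The comparison of MG132 with control asked how inhibition of the proteasome changed expression. The highest ratios were those of CRYAB, a small heat shock protein (5.17 ± 0.07, 35.9-fold), the stress transcription factors DDIT3 (4.52 ± 0.10) and ATF3 (4.33 ± 0.13), the ferritin light chain FTL (3.95 ± 0.11), MLLT11 (3.94 ± 0.10) and the heme oxygenase HMOX1 (3.89 ± 0.10). GEM (3.81 ± 0.07), the zinc finger factor KLF6 (3.78 ± 0.14), the iron carrier LCN2 (3.71 ± 0.12) and the heat shock protein HSPA6 (3.67 ± 0.11) followed, all with adjusted p of 1.39e-07 or less. The lowest were the calcium-binding protein S100A8 (−4.62 ± 0.14), CLIC3 (−3.92 ± 0.13), the collagen COL12A1 (−3.24 ± 0.14), the repressor TRPS1 (−3.19 ± 0.14) and the secreted protein PIP (−3.05 ± 0.28). Next came the potassium channels KCNS3 (−3.04 ± 0.11) and KCNK2 (−3.02 ± 0.11), CRIP1 (−3.04 ± 0.11, −2.85 at its other probe), the lipogenic regulator SREBF1 (−2.99 ± 0.12) and the selenium carrier SELENOP (−2.97 ± 0.19), with adjusted p of 2.34e-05 or less.

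Of 33 measured cytosolic and mitochondrial chaperones, 30 rose with MG132 and none fell (median 1.11, camera adjusted p = 2.89e-10, but 0.398 with an estimated correlation), among them HSPA1A (2.80 ± 0.09, and 2.20 at its other probe), HSPA1L (2.05 ± 0.07) and the index gene DNAJB1 (2.79 ± 0.12). In the unfolded protein and integrated stress response list 19 of 25 rose and 2 fell (median 1.36, camera adjusted p = 0.000157, but 0.398 with an estimated correlation). HYOU1 rose 3.25-fold, and HSPA5, the endoplasmic reticulum chaperone BiP, was saturated in every treated channel and rose at least 6.78-fold. XBP1, named after its value was seen, fell (−1.35). Of 42 proteasome genes 30 rose and 6 fell (median 0.77, camera adjusted p = 0.000128, but 0.498 with an estimated correlation). PSMC6 was at 1.89 ± 0.09, PSMD14 at 1.78 ± 0.10, PSMD1 at 1.14 ± 0.07 and PSMD12 at 1.85 ± 0.09, whose other probe read 0.30. Among those that fell were the interferon-inducible catalytic subunit PSMB10 (−1.77) and the activator subunits PSME2 (−1.57) and PSME1 (−1.35), also named after their values were seen. NRF2 response genes rose in 13 of 24 cases and fell in 4 (median 0.43, camera adjusted p = 0.000402, but 0.398 with an estimated correlation), with the glutathione synthesis subunit GCLM at 2.77 ± 0.09 and the exporter ABCC2 at 1.99 ± 0.07. The autophagy receptor SQSTM1 rose by 2.12 ± 0.08 and the cyclin-dependent kinase inhibitor CDKN1A by 2.57 ± 0.08.

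Of 45 cell cycle genes 32 fell and 3 rose (median −0.73, camera adjusted p = 5.67e-06, but 0.398 with an estimated correlation). UBE2C was at −1.87 ± 0.12, the replication helicase subunit MCM6 at −1.63 ± 0.10, the kinetochore gene NDC80 at −1.30 ± 0.09, KIF20A at −1.15 ± 0.08 and MKI67 at −0.73 ± 0.17. Without MG132 replicate 2 MKI67 read −0.57 and lost its call. Histone genes fell in 32 of 42 cases and rose in 5 (median −0.90, camera adjusted p = 1.04e-06, but 0.398 with an estimated correlation), including H3C6 (−1.72 ± 0.09), H3C1 (−1.37 ± 0.10), H2AZ2 (−1.34 ± 0.10) and MACROH2A2 (−1.02 ± 0.08). Of 13 luminal markers 8 fell and 4 rose (median −0.71, camera adjusted p = 0.0135, but 0.498 with an estimated correlation). The 9 markers with complete ratios had a median of −1.36. Keratin KRT19 was at −2.93 ± 0.12, the pioneer factor FOXA1 at −2.18 ± 0.13, TFF3 at −1.36 ± 0.09 and CLDN3 at −1.13 ± 0.12. Metallothioneins fell in 6 of 10 cases (median −0.28, camera adjusted p = 0.00436, but 0.398 with an estimated correlation). MT2A was at −1.36 ± 0.07, MT1G at −0.99 ± 0.08, MT1E at −0.98 ± 0.09 and MT1H at −0.89 ± 0.08 (−0.29 at its other probe). Of 16 estrogen-repressed genes 9 fell and 3 rose (median −0.34, camera adjusted p = 0.0195, but 0.398 with an estimated correlation). The named members went both ways, with INHBB at −2.28 ± 0.09 and ERBB2 at −1.45 ± 0.07 against KLF4 at 1.19 ± 0.07. The estrogen-responsive progesterone receptor gene PGR fell (−2.27 ± 0.17), and CTSD (−0.88 ± 0.14) and CXCL12 (−0.58 ± 0.15, above background in 3 of 4 treated channels) were also lower. Without MG132 replicate 1 CXCL12 read −0.22 and lost its call.

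Other lists moved both ways or were not called by camera. Among p53 targets 9 of 21 rose and 5 fell (adjusted p = 0.258), with GDF15 at 3.60 ± 0.12 and GADD45A at 3.21 ± 0.10 but PLK2 at −2.42 ± 0.08. Of 33 nuclear receptors 6 rose and 10 fell (adjusted p = 0.515). NR2F1 was at −2.49 ± 0.16, NR2F2 at −2.29 ± 0.10, the androgen receptor AR at −1.55 ± 0.10 and THRA at −1.27 ± 0.10. The receptors of both hormones, ESR1 (−0.03 ± 0.08) and NR3C1 (0.01 ± 0.10), were not called. The ESR1 probe was dim, so a change cannot be excluded. Its reading of 0.42 on the arrays with treated RNA in Cy3 alone keeps the dye bias of the probe and is no evidence of a change. Interferon-stimulated genes fell in 11 of 14 cases and rose in 2 (median −0.68, camera adjusted p = 0.573). IFITM1 was at −2.69 ± 0.09 and OAS2 at −2.25 ± 0.10, against IFIT2 at 2.48 ± 0.11 and ISG20 at 2.32 ± 0.11, while fry, in contrast to the median and camera, gave an upward balance (adjusted p = 0.0345). Higher and lower members numbered 6 and 2 of 19 for NF-kB targets, 11 and 14 of 37 for apoptosis, 9 and 3 of 22 for autophagy, 5 and 7 of 16 for cholesterol synthesis, 23 and 25 of 79 for chromatin-modifying enzymes and 9 and 7 of 29 for coregulators. They numbered 21 and 7 of 45 for ubiquitin genes, 13 and 3 of 70 for ribosomal proteins, 10 and 13 of 35 for estrogen-induced genes and 6 and 9 of 28 for glucocorticoid-induced genes. Markers of basal cells (4 and 1 of 9), fibroblasts (3 and 2 of 13) and leukocytes (3 and 2 of 14) were not called by camera either, and the lowest adjusted p of all lists not called was 0.181, for ribosomal proteins.

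In all, limma called 7861 of 16085 probes with MG132, 4005 higher and 3856 lower, and 1389 of them changed by at least 2-fold. With extraction day as a block, 6081 of 13275 complete probes were called (3096 higher, 2985 lower), and all 9 list calls held. Adjusted over the list alone, the counts were equal except for NRF2 (14 higher, 4 lower), cell cycle (3 and 33), histones (6 and 32), metallothioneins (1 and 7), ubiquitin genes (22 and 8), chromatin enzymes (23 and 26), ribosomal proteins (10 and 3) and leukocyte markers (3 and 1). No list was called with an estimated correlation.

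**Figure D1:**
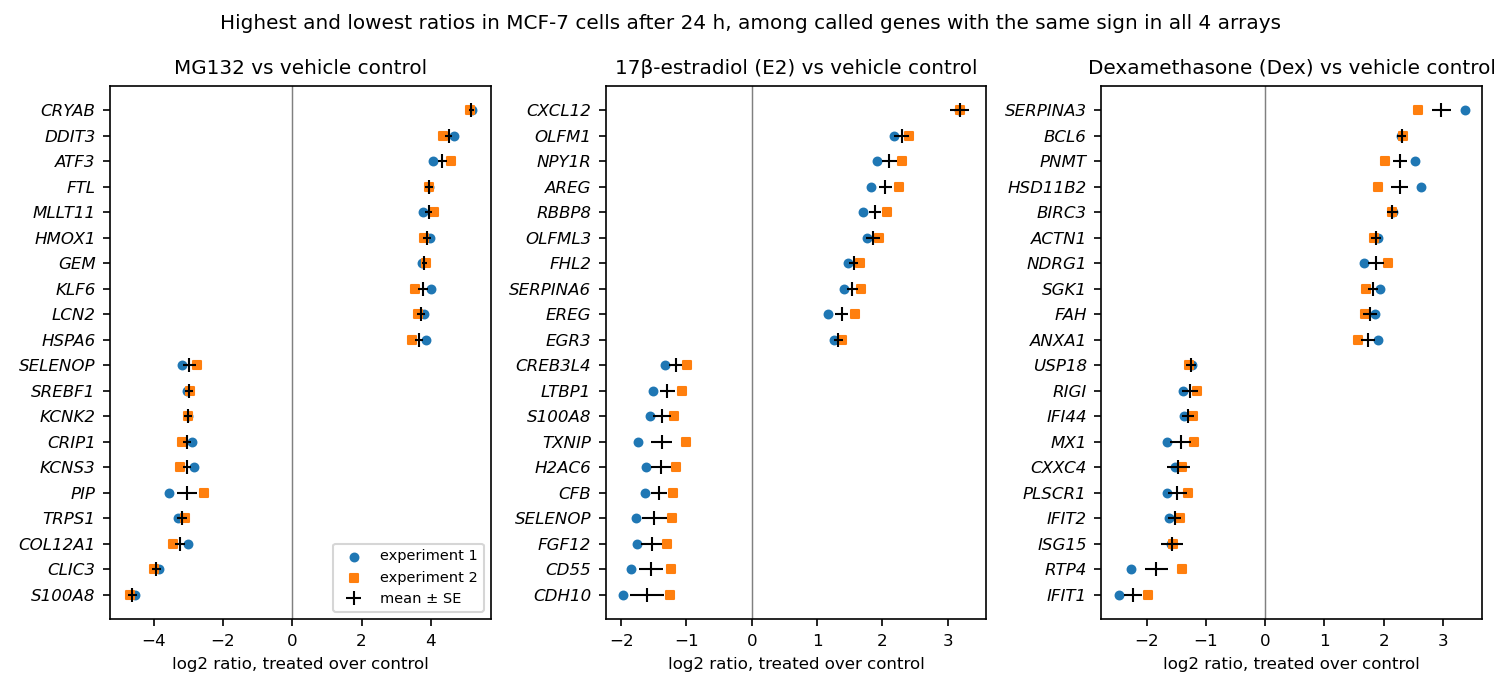
Log2 ratios of treated over control RNA for the 10 highest and 10 lowest of the genes called with the same sign in all 4 arrays for MG132, E2 and dexamethasone. Circles and squares are the replicate ratios of experiments 1 and 2 and black marks their mean ± SE; both experiments lie on the same side of 0 for every gene shown, and MG132 spans 5.17 (CRYAB) to −4.62 (S100A8).

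E2 raised the chemokine gene CXCL12 (3.18 ± 0.15, 9.06-fold), OLFM1 (2.29 ± 0.11), the neuropeptide Y receptor NPY1R (2.11 ± 0.12) and the EGF receptor ligands AREG (2.04 ± 0.10) and EREG (1.37 ± 0.10). It also raised the DNA end resection factor RBBP8 (1.89 ± 0.09), OLFML3 (1.85 ± 0.11), FHL2 (1.56 ± 0.07), the corticosteroid-binding globulin SERPINA6 (1.54 ± 0.08) and EGR3 (1.32 ± 0.07), with adjusted p of 5.31e-05 or less. It lowered CDH10 (−1.61 ± 0.26), the complement regulator CD55 (−1.55 ± 0.18), FGF12 (−1.53 ± 0.16, −1.38 at its other probe) and SELENOP (−1.49 ± 0.19). Lower, too, were complement factor CFB (−1.42 ± 0.12), H2AC6 (−1.39 ± 0.15), the thioredoxin-binding protein TXNIP (−1.38 ± 0.16), S100A8 (−1.38 ± 0.14), LTBP1 (−1.29 ± 0.12) and CREB3L4 (−1.17 ± 0.10), with adjusted p of 0.00380 or less. CDH10 lost its call without E2 replicate 1 (−1.24, adjusted p = 0.0509). Of 35 estrogen-induced genes fixed beforehand 15 rose and none fell (17 adjusted over the list alone, median 0.26, adjusted p = 0.00963 with an estimated correlation), PGR among them at 0.82 ± 0.17. Without E2 replicates 1 and 2 PGR read 0.83 and 0.82 and lost its call. The classical target TFF1 read 0.05 ± 0.09 and ESR1 −0.02 ± 0.08, both on dim probes. On the arrays with treated RNA in Cy3 alone, which keep the dye bias of a probe, ESR1 read 0.41. Of 16 estrogen-repressed genes 7 fell and none rose (8 adjusted over the list alone, camera adjusted p = 3.03e-05, but 0.197 with an estimated correlation), among them ERBB2 (−1.07 ± 0.10), CCNG2 (−1.07 ± 0.08), TP53INP1 (−0.76 ± 0.07) and EFNA1 (−0.65 ± 0.08).

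Cell cycle genes rose in 32 of 45 cases and none fell (33 adjusted over the list alone, median 0.58, adjusted p = 0.0946 with an estimated correlation). The spindle checkpoint gene MAD2L1 was at 0.92 ± 0.11, cyclin CCNA2 at 0.66 ± 0.07, RRM2 at 0.64 ± 0.07 and KIF23 at 0.62 ± 0.08. Of 70 ribosomal protein genes 27 rose and none fell (46 adjusted over the list alone, adjusted p = 0.302 with an estimated correlation), with RPS6 at 0.89 ± 0.11, RPL5 at 0.73 ± 0.10 and RPL4 at 0.67 ± 0.07. Of 33 chaperones 13 rose and none fell (17 higher and 2 lower adjusted over the list alone, adjusted p = 0.298 with an estimated correlation). They were led by the mitochondrial pair HSPD1 (1.09 ± 0.08) and HSPE1 (0.87 ± 0.10), the steroid receptor co-chaperone FKBP4 (0.90 ± 0.08) and HSPA8 (0.64 ± 0.11). The call of HSPA8 was lost without E2 replicate 2 (0.47). Histone genes fell in 18 of 42 cases and 1 rose (20 and 4 adjusted over the list alone, adjusted p = 0.302 with an estimated correlation). H2AC8 was at −0.99 ± 0.12 (−0.62 at its other probe), H2BC21 at −0.93 ± 0.11 and H2AC11 at −0.77 ± 0.11, which had this sign in 3 of 4 arrays. Metallothioneins rose in 5 of 10 cases, the same number adjusted over the list alone (adjusted p = 0.302 with an estimated correlation), with MT1A at 0.45 ± 0.09 and MT1H at 0.37 ± 0.08 (0.43 at its other probe). Without E2 replicate 2 MT1A (0.36), MT1G (0.23), MT1H (0.30) and MT2A (0.30) lost their calls. Camera called these 5 lists only at its preset correlation.

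For E2 limma called 1619 probes, 926 higher and 693 lower, and 65 changed by at least 2-fold. The share of calls that were higher grew without E2 replicate 1 and shrank without E2 replicate 2. The count was 2528 (1262 higher, 1266 lower) with the replicate block and 1182 of 13275 (705 higher, 477 lower) with day as a block, which kept all 7 list calls. Without E2 replicate 2 it was 723 (290 higher, 433 lower).

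Dexamethasone raised the acute-phase inhibitor SERPINA3 (2.97 ± 0.16, 7.85-fold), the repressor BCL6 (2.30 ± 0.07), the adrenaline-synthesising enzyme PNMT (2.27 ± 0.12), and HSD11B2, which inactivates cortisol (2.27 ± 0.15). It also raised the apoptosis inhibitor BIRC3 (2.14 ± 0.09), ACTN1 (1.87 ± 0.09), NDRG1 (1.87 ± 0.14), the kinase SGK1 (1.82 ± 0.09), FAH (1.77 ± 0.12) and annexin ANXA1 (1.73 ± 0.12), with adjusted p of 7.67e-05 or less. Among genes with the same sign in all 4 arrays, the lowest ratios were mostly those of genes known to respond to interferon: IFIT1 (−2.23 ± 0.15), RTP4 (−1.83 ± 0.19), ISG15 (−1.58 ± 0.18), IFIT2 (−1.53 ± 0.11), PLSCR1 (−1.48 ± 0.16), MX1 (−1.43 ± 0.18), IFI44 (−1.30 ± 0.10), the RNA sensor RIGI (−1.27 ± 0.13) and USP18 (−1.25 ± 0.08), together with CXXC4 (−1.46 ± 0.19). Their adjusted p was 0.00202 or less. Without Dex replicate 1, MX1 (−1.19) and CXXC4 (−1.40) kept their direction and most of their size, and their adjusted p was 0.0544 and 0.0614. ISG15 missed the threshold on the arrays with treated RNA in Cy3 alone (−0.62, adjusted p = 0.0506).

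Of 28 glucocorticoid-induced genes fixed beforehand 17 rose and none fell (18 adjusted over the list alone, median 0.49, adjusted p = 0.00791 with an estimated correlation). PER1 rose by 0.41 ± 0.07 and CDKN1A by 0.80 ± 0.08, while TSC22D3 (0.16 ± 0.08) and ZBTB16 (0.18 ± 0.08) were not called. PER1 lost its call without Dex replicates 1 and 2 (0.46 and 0.36). FKBP5, the index gene with too few usable spots for a fit, read 1.78 and 2.37 on its only usable array of each experiment. Of 14 interferon-stimulated genes 9 fell and none rose (12 adjusted over the list alone, median −1.27, camera adjusted p = 5.1e-10, but 0.0843 with an estimated correlation), OAS2 among them at −1.69 ± 0.14. Metallothioneins rose in 7 of 10 cases (8 adjusted over the list alone, median 0.64, camera adjusted p = 4.87e-10, but 0.0843 with an estimated correlation). MT1B was at 1.03 ± 0.07, MT1H at 0.93 ± 0.08 (1.16 at its other probe), MT1A at 0.68 ± 0.09 and MT2A at 0.60 ± 0.07. MT1A lost its call without Dex replicate 1 (0.61). Cell cycle genes fell in 7 of 45 cases (10 adjusted over the list alone, camera adjusted p = 5.96e-08, but 0.26 with an estimated correlation), with TYMS at −0.64 ± 0.11 and MCM3 at −0.52 ± 0.09. TYMS (−0.78 and −0.50) and MCM3 (−0.60 and −0.43) lost their calls without Dex replicates 1 and 2. Camera also called 4 other lists. Ribosomal proteins rose in 7 of 70 cases (18 adjusted over the list alone, median 0.22, camera adjusted p = 2.52e-10, but 0.562 with an estimated correlation). RPL13 (0.53 ± 0.10), RPL5 (0.50 ± 0.10), RPL4 (0.45 ± 0.07) and RPS3A (0.41 ± 0.08) lost their calls without either Dex replicate (adjusted p of 0.0844 to 0.203). Estrogen-repressed genes fell in 3 of 16 cases and rose in 1 (4 and 2 adjusted over the list alone, median −0.15, camera adjusted p = 0.000930, but 0.26 with an estimated correlation). TGFB3 (−0.91 ± 0.12), EFNA1 (−0.45 ± 0.08, this sign in 3 of 4 arrays) and BLNK (−0.27 ± 0.06) were lower and KLF4 (0.51 ± 0.07) was higher. Without Dex replicates 1 and 2 the adjusted p was 0.0767 and 0.168 for EFNA1 and 0.374 and 0.237 for BLNK, and KLF4 missed the threshold without the latter (0.0551). Chaperones rose in 3 of 33 cases (5 higher and 1 lower adjusted over the list alone, median 0.10, camera adjusted p = 0.0162, but 0.562 with an estimated correlation), a call lost without Dex replicate 2 (adjusted p = 0.238). CRYAB was at 1.60 ± 0.07, HSPD1 at 0.55 ± 0.08 and HSPE1 at 0.43 ± 0.10, and without Dex replicate 2 HSPD1 and HSPE1 were not called (adjusted p = 0.0870 and 0.376). Histone genes fell in 3 of 42 cases (8 adjusted over the list alone, median −0.17, camera adjusted p = 0.00147, but 0.562 with an estimated correlation), and turned to a median of 0.32 on the arrays with treated RNA in Cy3 alone. H4C11 was at −0.56 ± 0.14 (this sign in 3 of 4 arrays, −0.29 to 0.03 at its other probes), H2BC11 at −0.35 ± 0.09 and H2BC9 at −0.30 ± 0.06 (this sign in 2 of 4 arrays, 0.60 on those with treated RNA in Cy3). None of the 3 was called without Dex replicate 2 (adjusted p = 0.690, 0.171 and 0.294). The basal keratins KRT6A (2.15 ± 0.11), KRT5 (0.73 ± 0.16) and KRT6B (0.50 ± 0.09, this sign in 3 of 4 arrays) rose, although camera did not call the list of 9 basal markers (adjusted p = 0.318). KRT5 lost its call without Dex replicates 1 and 2 (0.92 and 0.53), and KRT6B without the latter (0.35). Of 42 proteasome genes 1 rose and 3 fell, and all 3 were interferon-inducible subunits, PSMB10 (−0.61 ± 0.14), PSMB8 (−0.66 ± 0.08) and PSMB9 (−0.49 ± 0.10); PSMB8 and PSMB9 had this sign in 2 of 4 arrays and turned to 0.42 and 0.69 on the arrays with treated RNA in Cy3 alone. Without Dex replicate 1 or 2, PSMB10 read −0.52 and −0.70 (adjusted p = 0.348 and 0.192) and PSMB9 −0.52 and −0.46 (adjusted p = 0.196 and 0.283).

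For dexamethasone limma called 941 probes, 575 higher and 366 lower, and 123 changed by at least 2-fold. The share of calls that were higher grew without either Dex replicate, more so without replicate 1. The count was 1517 (864 higher, 653 lower) with the replicate block and 1317 of 13275 (753 higher, 564 lower) with day as a block. The latter kept all 8 list calls, but could not change their medians by construction. The count was 2095 (1067 higher, 1028 lower) with only the dexamethasone replicates in the fit. It was 263 without Dex replicate 1 and 341 without Dex replicate 2.

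**Figure D2:**
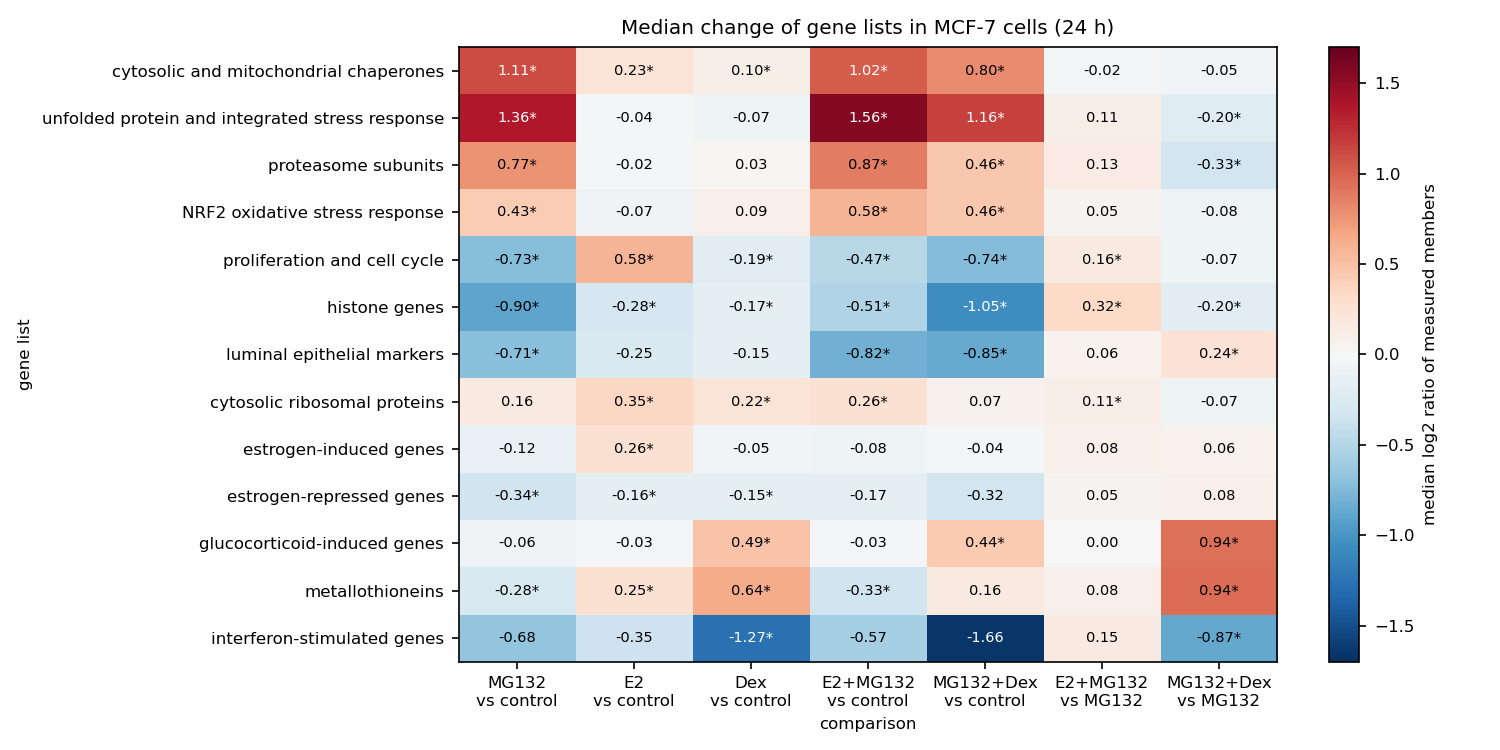
Median log2 change of the measured members of 13 gene lists in 7 comparisons; blue is lower and red higher, and an asterisk marks a camera adjusted p under 0.05. Medians cover all measured members, but asterisks rest only on members with complete ratios. Chaperones are at 1.11, 1.02 and 0.80 in the 3 treatments with MG132. The 17 chaperones with complete ratios were at 1.44 with MG132, 1.48 with E2 and MG132, and 1.74 with MG132 and dexamethasone. Glucocorticoid-induced genes are at 0.49 with dexamethasone and 0.94 when it was added to MG132.

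E2 with MG132 against control raised DDIT3 (4.78 ± 0.10), CRYAB (4.56 ± 0.07), ATF3 (4.26 ± 0.13), LCN2 (4.07 ± 0.12) and FTL (adjusted p = 1.40e-08) most. It lowered S100A8 (−4.35 ± 0.14), CLIC3 (−3.67 ± 0.13, above background in 3 of 4 treated channels), BZW2 (−3.26 ± 0.08), TRPS1 (−3.20 ± 0.14) and COL12A1 (−3.16 ± 0.14). MG132 with dexamethasone raised CRYAB (6.08 ± 0.07, 67.8-fold), KLF6 (4.28 ± 0.14), the phosphatase DUSP1 (4.09 ± 0.12), keratin KRT75 (3.99 ± 0.15) and ANXA1 (3.98 ± 0.12). It lowered S100A8 (−4.75 ± 0.14), SEMA3C (−3.88 ± 0.07), CLIC3 (−3.32 ± 0.13), KCNK2 (−3.14 ± 0.11) and COL12A1 (−3.08 ± 0.14). PGR was at −1.90 ± 0.17 with E2 and MG132 and at −2.46 ± 0.24 with MG132 and dexamethasone, where NR3C1 was also lower (−0.35 ± 0.10). Without MG132 + Dex replicate 1 NR3C1 read −0.19 and lost its call.

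For E2 with MG132 limma called 8360 probes (4327 higher, 4033 lower) and for MG132 with dexamethasone 7365 (3830 higher, 3535 lower). With day as a block these were 6944 and 6533 of 13275, with the calls of all 9 and all 8 lists kept. With an estimated correlation none of these lists was called. Of these lists 8 and 7 were among the 9 called with MG132 alone, in the same direction. The others were ribosomal proteins with E2 and MG132 (34 higher and 2 lower of 70, as adjusted over the list alone, median 0.26, camera adjusted p = 0.00393, but 0.878 with an estimated correlation) and glucocorticoid-induced genes with MG132 and dexamethasone (19 higher and 1 lower of 28, as adjusted over the list alone, median 0.44, camera adjusted p = 5.32e-05, but 0.112 with an estimated correlation). E2 with MG132 gave 5309 calls without its replicate 1 and 5011 without its replicate 2. Across 13275 probes the changes of MG132 and of E2 with MG132 correlated at r = 0.97. Unchanged groups with a shared control gave 0.50 in simulation (covariance 0.277 against 0.00440). That r follows from its setting, in which treated and control RNA held equal parts of the spread. In the data, the deviations of 2 treatments correlated at a median of 0.27. Those of MG132 and MG132 with dexamethasone correlated at 0.86 (covariance 0.239 against 0.00439). E2 and dexamethasone correlated at 0.21 (covariance 0.00941 against 0.00440), and 131 probes were called higher and 114 lower with both, and 68 in opposite directions, against 33.1, 15.8 and 45.8 for independent lists. Genes are not independent replicates, the control could not be split, and part of these overlaps may come from the shared control RNA.

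Among genes with the same sign in all 4 arrays, adding MG132 in the presence of E2 raised DDIT3 (4.84 ± 0.14), LCN2 (4.83 ± 0.18), FTL (4.26 ± 0.16), ATF3 (4.01 ± 0.19) and MLLT11 (3.85 ± 0.15) most, while CRYAB, with a single E2 ratio, was at 4.88 ± 0.12. It lowered COL12A1 (−4.44 ± 0.19), CXCL12 (−4.06 ± 0.21), CLIC3 (−3.20 ± 0.18), OLFM1 (−3.12 ± 0.16) and TRPS1 (−3.07 ± 0.20). Estrogen-induced genes fell in 17 of 35 cases and rose in 4 (18 and 4 adjusted over the list alone, camera adjusted p = 0.000298; adjusted p = 0.175 with an estimated correlation). EGR3 was at −1.28 ± 0.10, against the small heat shock protein HSPB8 at 2.46 ± 0.14. Of 45 cell cycle genes 40 fell and 2 rose (40 and 3 adjusted over the list alone, camera adjusted p = 1.75e-11; adjusted p = 0.204 with an estimated correlation). MCM6 was at −2.01 ± 0.15, cyclin CCNB2 at −2.00 ± 0.14, NDC80 at −1.67 ± 0.13 and RRM2 at −1.64 ± 0.10. In the presence of dexamethasone, MG132 raised CRYAB (4.48 ± 0.10), DDIT3 (4.21 ± 0.14), HMOX1 (3.77 ± 0.15), ATF3 (3.65 ± 0.19) and TCIRG1 (3.51 ± 0.32) most. It lowered S100A8 (−5.98 ± 0.20), COL12A1 (−3.45 ± 0.19), CLIC3 (−3.26 ± 0.18), SATB1 (−3.04 ± 0.14, −2.66 at its other probe) and S100A9 (−2.97 ± 0.18).

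For MG132 limma called 5804 probes on E2 (3255 higher, 2549 lower) and 5139 on dexamethasone (2537 higher, 2602 lower). With day as a block these were 3874 and 5155 of 13275, which kept 8 of 8 and 6 of 8 list calls. No list was called in either comparison with an estimated correlation. On E2, 6 of the 8 lists were among the 9 called with MG132 alone, in the same direction, and on dexamethasone all 8. The others on E2 were estrogen-induced genes and NF-kB targets (6 higher and none lower of 19, as adjusted over the list alone, median 0.32, camera adjusted p = 0.0277, but 0.231 with an estimated correlation). The count on E2 was 3733 without E2 + MG132 replicate 2, and that on dexamethasone 2885 without Dex replicate 2. These 2 comparisons share no RNA, and their changes correlated at 0.75 across probes against 0.000519 in simulation. The simulation held no dye or day bias, so its low value follows from its setting. Those of MG132 alone correlated at 0.88 with MG132 on E2 and at 0.83 with MG132 on dexamethasone, again without shared RNA. Probes called higher with MG132 alone had a median of 0.50 alone, 0.52 on E2 and 0.37 on dexamethasone, and those called lower −0.54, −0.43 and −0.46.

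When E2 was added to MG132, 642 of 16085 probes had an unadjusted limma p under 0.05, fewer than the 5% that no effect would give. Too wide an error can give such a deficit, so it is no evidence for no effect. The shared spread holds the control's, which cancels here. It also pools replicates that differed more, with an SD of 0.255 for E2 and 0.229 for MG132 with dexamethasone. For the compared treatments this SD was 0.190 (MG132) and 0.159 (E2 with MG132). No probe passed limma's threshold. The count was 0 under every other setting run, including the replicate block, day as a block (0 of 13275) and the arrays as units. CXCL12 read −0.30 ± 0.21, PGR 0.37 ± 0.24 and the estrogen-induced genes IGFBP4 0.77 ± 0.23 and HSPB8 0.39 ± 0.14, the largest of a list whose median was 0.08 (camera adjusted p = 0.535). Camera called histone genes (median 0.32, adjusted p = 2.37e-09), ribosomal proteins (median 0.11) and cell cycle genes (median 0.16), both with adjusted p = 0.00144. The adjusted p was 0.835, 0.844 and 0.835 with an estimated correlation, and the call of ribosomal proteins was lost with day as a block (median 0.04, adjusted p = 0.423). No member was called over all genes, and adjusted over the list alone 12 of 42 histone genes were higher, none of the 70 ribosomal and none of the 45 cell cycle genes; H1-10 read 0.72 ± 0.24 and H2AC16 0.64 ± 0.19.

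The 926 probes that E2 raised alone had a median of 0.48 and read 0.05 when E2 was added to MG132, and the 693 that it lowered had −0.46 and 0.11. These probes were picked by their call with E2 alone, which enlarges the first value of each. With MG132 alone, against the same controls, the raised probes had a median of −0.12 (252 called higher, 395 lower). The lowered ones had −0.52 (110 called higher, 455 lower). The interaction itself was called for 227 probes (125 higher, 102 lower). CXCL12 (−3.48 ± 0.25), OLFM1 (−2.09 ± 0.20), OLFML3 (−1.85 ± 0.18), AREG (−1.79 ± 0.18) and NPY1R (−1.76 ± 0.21) lost most or all of their rise. FGF12 (1.97 ± 0.28, 1.69 at its other probe), CFB (1.81 ± 0.21), S100A8 (1.65 ± 0.24), H2AC16 (1.52 ± 0.23) and TXNIP (1.43 ± 0.27) lost their fall. On MG132 the E2 effects of the latter lay between 0.06 (TXNIP) and 0.64 (H2AC16), none of them called. MG132 alone had lowered FGF12 (−2.16) and, more than any other gene ranked above, S100A8. Whether a further fall with E2 could be read at such lowered levels was not tested. Estrogen-induced genes had a lower response in 7 of 35 cases and a higher one in none (9 adjusted over the list alone, adjusted p = 0.0183 with an estimated correlation). FHL2 was at −1.45 ± 0.12 and EGR3 at −1.20 ± 0.12. Camera also called estrogen-repressed genes (5 of 16 higher, 8 adjusted over the list alone; ERBB2 1.25 ± 0.14), histones (12 of 42 higher, 20 higher and 1 lower adjusted over the list alone; H2BC21 1.36 ± 0.19) and chaperones (4 of 33 lower, 7 adjusted over the list alone; HSPD1 −1.32 ± 0.13). With an estimated correlation their adjusted p was 0.222, 0.252 and 0.282. Its calls further covered cell cycle genes (median −0.37, camera adjusted p = 6.84e-10, but 0.252 with an estimated correlation), of which 1 of 45, RRM2 (−0.80 ± 0.13), was lower (11 adjusted over the list alone). Ribosomal proteins (median −0.23, camera adjusted p = 4.56e-07, but 0.558 with an estimated correlation) had no called member. Interferon-stimulated genes (median 0.51, camera adjusted p = 0.0196, but 0.407 with an estimated correlation) had none over all genes and 6 higher of 14 adjusted over the list alone.

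The interaction count was unsteady. It was 714 (427 higher, 287 lower) with the replicate block, 571 of 13275 (250 higher, 321 lower) with day as a block, which kept 7 of 7 list calls, 452 with the arrays as units and 125 with trend and robust. It fell to 123 and 17 without MG132 replicates 1 and 2, to 25 and 10 without E2 + MG132 replicates 1 and 2, and to 103 and 107 without Dex replicates 1 and 2. Of 24 named genes with a called E2 interaction, CXCL12, OLFM1, OLFML3, AREG and FHL2 were called under every setting in which they were tested. The call was lost for 17 without E2 + MG132 replicate 2, for 16 without MG132 replicate 2, for 10 of 23 without E2 + MG132 replicate 1 and for 9 without MG132 replicate 1. In these 4 fits the changes lay between 85.4% and 115% of those reported. The call was lost for 5 of 23 without Dex replicate 1, 4 of 22 without Dex replicate 2, 2 of 23 without E2 replicate 1 and 3 without E2 replicate 2. It was lost for 7 with trend and robust and for 13 on the arrays with treated RNA in Cy3 alone, and no direction reversed. The share of calls that were higher was 55.1% and moved both ways. It was 71.2% with median centring, 71.7% without E2 replicate 2, 43.8% with day as a block, 38.4% with trend and robust, 28% without E2 + MG132 replicate 1, 25.4% without E2 replicate 1, 11.8% without MG132 replicate 2 and 0% without E2 + MG132 replicate 2.

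**Figure D3:**
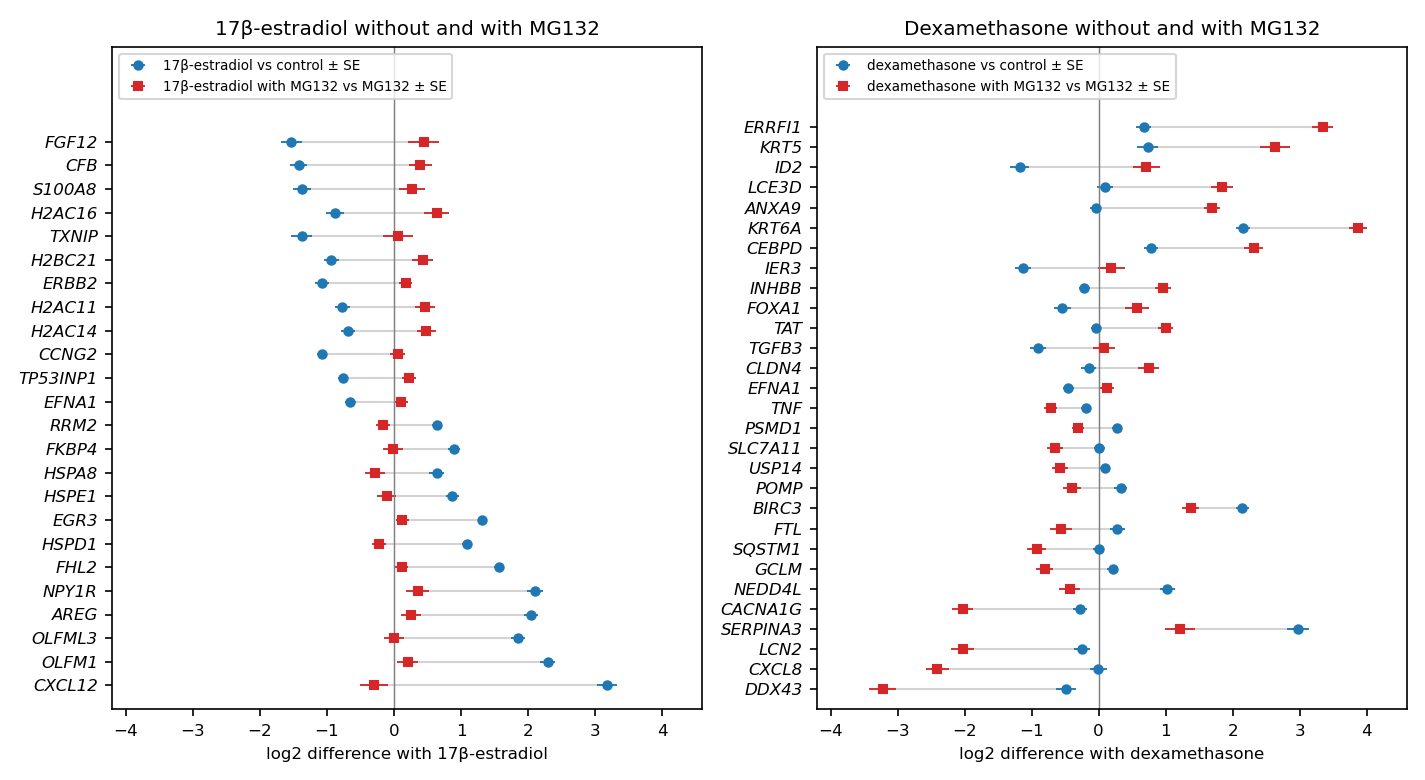
Log2 change ± SE with E2 (left) or dexamethasone (right), without MG132 (circles, against control) and with it (squares, against MG132), for named genes with a called interaction. With MG132 the E2 effects lie between −0.30 (CXCL12, 3.18 without MG132) and 0.64 (H2AC16). Dexamethasone effects change both ways, as for ERRFI1 (0.67 against 3.34) and CXCL8 (0.00 against −2.41).

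Added to MG132, dexamethasone raised the transcription factor MAFB (3.52 ± 0.15, 11.4-fold), ANXA1 (3.46 ± 0.17), the EGF receptor inhibitor ERRFI1 (3.34 ± 0.16) and the keratins KRT5 (2.63 ± 0.23) and KRT75 (2.47 ± 0.21), with adjusted p of 0.000140 or less. It lowered DDX43 (−3.22 ± 0.20), the neutrophil chemokine CXCL8 (−2.41 ± 0.17), the calcium channel CACNA1G (−2.03 ± 0.15), LCN2 (−2.03 ± 0.18) and the antiviral gene RSAD2 (−1.88 ± 0.12). Of 28 glucocorticoid-induced genes 16 rose and 1, LCN2, fell (22 and 1 adjusted over the list alone, median 0.94, adjusted p = 0.00553 with an estimated correlation). CEBPD was at 2.31 ± 0.14, SGK1 at 1.47 ± 0.12 and PER1 at 0.60 ± 0.10, whose call was lost without MG132 replicate 1 (0.55). Of 14 interferon-stimulated genes 8 fell (12 adjusted over the list alone, median −0.87, camera adjusted p = 9.5e-07, but 0.183 with an estimated correlation). Among them were IFIT1 (−2.48 ± 0.27), IFIT2 (−1.76 ± 0.16), IFI44 (−1.75 ± 0.17) and ISG20 (−1.09 ± 0.15). Metallothioneins rose in 6 of 10 cases (7 adjusted over the list alone, median 0.94, camera adjusted p = 3.17e-10, but 0.0866 with an estimated correlation). MT1H was at 1.46 ± 0.11 (0.92 at its other probe), MT1E at 1.18 ± 0.13, MT1B at 1.07 ± 0.10 and MT2A at 1.03 ± 0.10.

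Keratins KRT6A (3.87 ± 0.14) and KRT6B (0.73 ± 0.13) also rose, although the list of 9 basal markers was not called by camera (adjusted p = 0.135). With day as a block camera did call this list (median 0.14 over 8 members, camera adjusted p = 0.0310). KRT6B lost its call without MG132 replicate 1 (0.63). Of 13 luminal markers 2 rose and none fell (4 adjusted over the list alone, median 0.24, camera adjusted p = 0.0109, but 0.391 with an estimated correlation), namely KRT19 (1.20 ± 0.17) and CLDN4 (0.75 ± 0.16), whose call was lost without either MG132 replicate (adjusted p = 0.179 and 0.132). Among 19 NF-kB targets 3 were higher and 5 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.0557). BIRC3 was at 1.37 ± 0.13, against CXCL3 at −0.95 ± 0.14 and TNF at −0.71 ± 0.10. Proteasome genes had a median of −0.33 (camera adjusted p = 1.15e-05; adjusted p = 0.391 with an estimated correlation). Of 42, 2, the same number adjusted over the list alone, were called lower, PSMB1 (−0.76 ± 0.17) and PSMC6 (−0.54 ± 0.13). Without MG132 replicates 1 and 2 PSMB1 (−0.79 and −0.73) and PSMC6 (−0.57 and −0.52) lost their calls. PSMC6 also lost its call without any single replicate of Dex, E2 + MG132 or MG132 + Dex. Camera's calls of histones (median −0.20, adjusted p = 0.0206), ubiquitin genes (median −0.13, adjusted p = 0.0440) and the unfolded protein and integrated stress response (median −0.20, adjusted p = 0.0454) were lost with day as a block (adjusted p = 0.293, 0.0553 and 0.103). Their adjusted p was 0.629, 0.660 and 0.391 with an estimated correlation. No histone gene of 42 was called, nor any adjusted over the list alone. Of 45 ubiquitin genes FBXO32 (0.75 ± 0.18) and USP14 (−0.57 ± 0.12) were called, 1 higher and 1 lower, as adjusted over the list alone, and neither without either MG132 replicate (adjusted p of 0.121 to 0.281). Of 25 stress response genes 2 were lower (5 adjusted over the list alone), SLC7A11 (−0.65 ± 0.12) and DDIT3, which were not called without MG132 + Dex replicate 1 (adjusted p = 0.0910 and 0.216). SQSTM1 (−0.93 ± 0.14) and DDIT3 (−0.62 ± 0.14) were lower too. In all limma called 730 probes (420 higher, 310 lower), 1234 (601 higher, 633 lower) with the replicate block and 629 of 13275 (373 higher, 256 lower) with day as a block, which kept 5 of 8 list calls. The count was 408 and 348 without MG132 replicates 1 and 2 and 478 without MG132 + Dex replicate 1.

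The 575 probes that dexamethasone raised alone had a median of 0.56 and read 0.18 on MG132, and the 366 that it lowered −0.51 and −0.05. These probes were picked by their call with dexamethasone alone, which enlarges the first value of each. Over all 13275 probes the 2 effects of dexamethasone, which share no RNA, correlated at 0.23, against −0.00200 in a simulation without dye or day bias. The interaction was called for 516 probes (252 higher, 264 lower). Responses were higher on MG132 for ERRFI1 (2.67 ± 0.19), KRT5 (1.90 ± 0.28), ID2 (1.89 ± 0.24), LCE3D (1.75 ± 0.20) and ANXA9 (1.74 ± 0.15), and lower for DDX43 (−2.73 ± 0.25), CXCL8 (−2.40 ± 0.21), LCN2 (−1.78 ± 0.21), SERPINA3 (−1.76 ± 0.28) and CACNA1G (−1.75 ± 0.19). Glucocorticoid-induced genes went both ways (4 higher and 4 lower of 28, 8 and 6 adjusted over the list alone, camera adjusted p = 0.103). CEBPD was at 1.53 ± 0.18 and TAT, a liver enzyme, at 1.03 ± 0.13. Camera called 8 lists. Ribosomal proteins (median −0.30, camera adjusted p = 3.80e-05, but 0.666 with an estimated correlation) had no called member, nor any adjusted over the list alone. Proteasome genes were lower in 2 of 42 cases (5 adjusted over the list alone, median −0.36, camera adjusted p = 0.000115, but 0.666 with an estimated correlation), POMP (−0.72 ± 0.16) and PSMD1 (−0.58 ± 0.12). Ubiquitin genes were lower in 2 of 45 (3 adjusted over the list alone, median −0.19, camera adjusted p = 0.00305, but 0.666 with an estimated correlation), NEDD4L (−1.46 ± 0.19) and USP14 (−0.66 ± 0.14). Estrogen-repressed genes were higher in 3 of 16 cases, the same number adjusted over the list alone (median 0.18, camera adjusted p = 0.000490, but 0.433 with an estimated correlation), INHBB (1.17 ± 0.15), TGFB3 (0.99 ± 0.20) and EFNA1 (0.57 ± 0.13, this sign in 3 of 4 arrays). Metallothioneins had no called member over all genes and 3 higher of 10 adjusted over the list alone (median 0.08, camera adjusted p = 0.0426, but 0.666 with an estimated correlation), a call lost with day as a block (adjusted p = 0.117). NF-kB targets (1 higher and 3 lower of 19, 2 and 5 adjusted over the list alone, camera adjusted p = 0.00381; IER3 1.31 ± 0.24) and NRF2 genes (4 of 24 lower, 1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0426; GCLM −1.01 ± 0.15) had adjusted p = 0.397 and adjusted p = 0.666 with an estimated correlation. Luminal markers were higher in 2 of 13 cases (4 adjusted over the list alone, median 0.46, camera adjusted p = 0.00447, but 0.666 with an estimated correlation), FOXA1 (1.12 ± 0.22) and CLDN4 (0.90 ± 0.19).

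This count was 1181 (527 higher, 654 lower) with the replicate block, 646 of 13275 (307 higher, 339 lower) with day as a block, which kept 7 of 8 list calls but lost 3 of 23 named genes, FOXA1, TNF and SERPINA3 (−1.31, adjusted p = 0.0656), and 894 with the arrays as units. SERPINA3 also lost its call without MG132 replicate 2 (−1.72, adjusted p = 0.0656). Of 29 named genes, 14 were called under every setting in which they were tested. The call was lost for 14 without MG132 replicate 2, 12 without MG132 replicate 1, 13 of 28 without Dex replicate 1 and 13 without Dex replicate 2. It was lost for 7 of 27 and 9 without E2 + MG132 replicates 1 and 2, for 7 of 26 and 4 of 28 without MG132 + Dex replicates 1 and 2, and for 11 with trend and robust. POMP, PSMD1, USP14, TGFB3, EFNA1, FOXA1 and CLDN4 were each lost without MG132 replicate 2. The count was 259 and 196 without MG132 replicates 1 and 2, 204 and 196 without Dex replicates 1 and 2, and 337 and 331 without E2 + MG132 replicates 1 and 2.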

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

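The tests on shared control RNA and on interferon-stimulated genes in the control RNA were chosen only after the result was seen. The genes and counts of the 2 paragraphs on interactions were picked up because limma's interaction test found that the effect of a hormone differed with and without MG132. The shared deviation of E2 and of MG132 with dexamethasone, and the lower interferon-stimulated genes with dexamethasone, came from other comparisons.

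For E2 the interaction was called for 227 probes and for dexamethasone for 516. The log2 difference between the E2 effect on MG132 and alone was −3.48 for CXCL12, −2.09 for OLFM1, −1.85 for OLFML3, −1.79 for AREG, −1.76 for NPY1R, −1.45 for FHL2, −1.20 for EGR3 and −0.80 for RRM2. Among chaperones it was −1.32 for HSPD1, −0.98 for HSPE1, −0.92 for HSPA8 and −0.91 for FKBP4. Genes that E2 lowered alone had a positive difference, 1.97 for FGF12, 1.81 for CFB, 1.65 for S100A8, 1.43 for TXNIP, 1.25 for ERBB2, 1.13 for CCNG2, 0.99 for TP53INP1 and 0.76 for EFNA1. Among histone genes it was 1.52 for H2AC16, 1.36 for H2BC21, 1.24 for H2AC11 and 1.17 for H2AC14.

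For dexamethasone the difference was −2.73 for DDX43, −2.40 for CXCL8, −1.78 for LCN2, −1.76 for SERPINA3, −1.75 for CACNA1G, −1.46 for NEDD4L, −1.01 for GCLM, −0.93 for SQSTM1, −0.84 for FTL, −0.77 for BIRC3, −0.72 for POMP, −0.66 for SLC7A11 and USP14, −0.58 for PSMD1 and −0.52 for TNF. It was 2.67 for ERRFI1, 1.90 for KRT5, 1.89 for ID2, 1.75 for LCE3D, 1.74 for ANXA9, 1.53 for CEBPD, 1.31 for IER3, 1.17 for INHBB, 1.12 for FOXA1, 1.03 for TAT, 0.99 for TGFB3, 0.90 for CLDN4 and 0.57 for EFNA1. For KRT6A it was 1.72, with this sign in 2 of 3 arrays. The values of ERBB2 and FKBP4 for E2, and of SQSTM1, IER3, USP14 and KRT6A for dexamethasone, rested on a single replicate ratio in at least 1 treatment. Many of these calls were lost when a replicate was left out, though no direction reversed.

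Few effects of E2 were seen on top of MG132. A wider error of this comparison would leave the size of the effects as it was. The probes that E2 raised alone kept 10.5% of their median change and those that it lowered −23.6%. These probes were picked by their call with E2 alone, which enlarges that change. The change alone also holds the control's spread, which cancels on MG132. Lower shares could thus arise with equal effects, and how far was not tested, so these shares did not decide. If E2 had been missing from the cultures with both agents, the E2 effect of one experiment should not correlate with that on MG132 in the other. This correlation across probes was 0.0929 in one order and −0.298 in the other, against 0.00102 in simulation, so the test did not decide. The 24 estrogen-induced genes with complete ratios, a list fixed beforehand, had a median of 0.27 with E2 alone and 0.08 on MG132. Camera called their interaction lower (median −0.33), also with an estimated correlation. These values, looked at after the result, argue against a wider error as the whole cause for these genes. A wider error may still contribute, and a missing hormone and a response to E2 lost with MG132 stay open.

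The deviations of E2 and of MG132 with dexamethasone between experiments were shared (r = 0.75 across probes). Control RNA shared by all treatments of an experiment should make every pair of treatments deviate together, but the smallest correlation was −0.108, which argues against it as the whole cause. The dye bias of an extraction day may contribute, since the profile of day 1 minus day 4 correlated with both deviations (the smaller r was 0.527). With the deviation of MG132, whose orientations lay on the days the other way round, r was −0.274. The r of the shared deviation was still 0.63 after removal of this profile. The profile came from a dexamethasone pair and a pair of E2 with MG132 and left out the other days. It therefore cannot show how much dye bias remained. What else the treatments shared was not tested, and no biological explanation was tested.

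Interferon-stimulated genes were lower with dexamethasone. High levels in the control RNA are argued against by the comparison of MG132 with dexamethasone against MG132, in which the control cancels and the list's median was −1.09 and −0.743 in the 2 experiments. Dye bias is argued against by the median on the arrays of either orientation, −1.11 and −0.889. A lower expression of these genes under the glucocorticoid may therefore be biological, as a hypothesis found and tested on the same data.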

How the results depend on the processing

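Removal of a dye profile was chosen only after the result was seen; its counts of called probes were all within 1.5 times those reported. Of 5837 values of named genes under settings that kept both dye orientations and all replicates, 5646 kept direction and side of the threshold, 143 fell short of it, 48 newly passed it and 0 reversed. With a single dye orientation the numbers were 835, 64, 38 and 11 of 948, and without a replicate 4258, 273, 24 and 0 of 4555; a treatment left with 1 replicate was assumed to vary like the others.

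Called probes with the replicate block were 2528 for E2, 1517 for dexamethasone, 1234 for MG132 with dexamethasone against MG132, and 714 and 1181 for the interactions of E2 and dexamethasone. With arrays as units the interactions gave 452 and 894. With trend and robust the E2 interaction gave 125, and with day as a block 571. Dexamethasone alone in the fit gave 2095. The cause was not tested. Arrays of a single orientation leave the dye bias of each gene in place by construction. With treated RNA in Cy5 they gave 6887 for E2, 6996 for dexamethasone, 3086 and 3848 for the interactions, and in Cy3 3934, 2940, 56 and 1279.

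Cy3 alone reversed PSMB8 (0.42), PSMB9 (0.69) and H2BC9 (0.60) with dexamethasone, DDIT3 (0.36), ESR1 (0.41) and MT2A (−0.0598) with E2, and ESR1 with MG132 (0.42) and with both (0.30). Cy5 alone reversed ZBTB16 with dexamethasone (−0.37), MG132 (−0.0436) and both (−0.17). With Cy3 alone camera's direction turned for histones with E2 (median −0.0169), dexamethasone (0.32) and in its interaction (−0.44), and for cholesterol genes in the E2 interaction (−0.32), but the median changed sign only for histones with dexamethasone. Fry's direction was opposite to camera's for interferon-stimulated genes with MG132 (median −0.75) and with E2 and MG132 (−0.60), and for estrogen-induced genes there (−0.0108); the cause was not tested.

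Called lists numbered 9 with MG132, 7 with E2, 8 with dexamethasone, 9 with E2 and MG132, 8 with MG132 and dexamethasone, 8 with MG132 on E2, 8 on dexamethasone, 3 with E2 on MG132, 8 with dexamethasone on MG132, and 7 and 8 in the interactions. With an estimated correlation they were 0, 1, 1, 0, 0, 0, 0, 0, 1, 1 and 0. Fry, which does not compare a list with other genes, called 16 with MG132, 11 with E2, 17 with each combination, 13 with MG132 on either hormone, 0 with E2 on MG132 and 3 in the dexamethasone interaction. With E2 on MG132 median centring called 7, its own treatments 5 and Cy5 5. Median centring called 5 with dexamethasone on MG132, Cy3 5 with E2 and MG132, Cy5 13 with MG132 and dexamethasone, and either dye 4 in the dexamethasone interaction.

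The correlation of MG132 with MG132 and dexamethasone was 0.897 for Cy3 and 0.831 with day as a block. That of E2 with dexamethasone was 0.737 for Cy5 and 0.649 for Cy3. MG132 against MG132 on E2 gave 0.670 for Cy5, and against MG132 on dexamethasone 0.583 for Cy5, 0.770 for Cy3 and 0.789 with day. E2 alone and on MG132 gave 0.325 for Cy3. Dexamethasone alone and on MG132 gave 0.0123 for Cy5, 0.0432 for Cy3 and 0.181 with day.

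Without a replicate, counts ranged from 723 to 1791 for E2, 263 to 1107 for dexamethasone, 5011 to 8616 for E2 with MG132, 3733 to 5894 for MG132 on E2, 2885 to 5486 for MG132 on dexamethasone, 348 to 900 for dexamethasone on MG132, 10 to 338 for the E2 interaction and 196 to 760 for the dexamethasone interaction. Called lists ranged from 5 to 9 for MG132 on dexamethasone and 2 to 5 for E2 on MG132. The correlations ranged from 0.827 to 0.865, 0.152 to 0.221, 0.845 to 0.899, 0.784 to 0.837, −0.272 to 0.141 and 0.164 to 0.283 in the order above. Dim probes limit what can be read, and ESR1 and TFF1 had mean log2 signals of 6.78 and 7.98.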

Other observations

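FKBP5, a classical glucocorticoid target, had log2 ratios of 0.98 and 1.30 in the 2 replicates of MG132 with dexamethasone, and 0.02 and −0.24 in those of MG132.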
